A study of Homo sapiens with 8 samples.

How the data were processed

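mRNA libraries from HGC27 gastric cancer cells overexpressing GFP or the p53 mutants R175H, R248Q or R273H were analysed, with 2 libraries per group and 8 in all. Per the labels, the authors prepared the libraries with a Kapa mRNA kit and processed the reads with bcl2fastq and STAR 2.5 on the hg19 build. The deposited values are raw read counts per gene, whole numbers with a different total in each library. The counting step, annotation release, strand setting and filters are not given in the sources used here, so genes that overlap on opposite strands and near-identical copies are uncertain. The table held 25435 gene symbols, of which 6937 had no count in any library, and 0 were duplicated.

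Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, leaving 13213. Libraries were scaled by TMM, with factors between 0.989 and 1.01, and a quasi-likelihood model with a mean per group was fitted to all 8 libraries, with 4 residual degrees of freedom, a median prior of 11.9 degrees of freedom and a common biological coefficient of variation of 4.51%. The 7 comparisons were each mutant against GFP, the mean of the 3 mutants against GFP, and each pair of mutants. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. SE values were derived from this model's test, as the absolute log2 fold change divided by the square root of the F statistic. SD values are between the 2 libraries of a group in TMM-normalised CPM.

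Total counts were 6800463 to 11788035 per library, so that 3 counts, taken as the floor of detection, were 0.307 CPM in GFP replicate 1. The most abundant gene, EEF2, took no more than 1.16% of any library. Replicates were compared by chi-square over genes with at least 20 counts. Correlations of replicate deviations between groups lay between -0.09 and 0.05, so libraries were not paired by replicate number.

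The comparisons, filters, alternatives, gene lists and rule for named genes were set before the data were examined. The 26 lists were: p53 activated targets, genes set down as induced by mutant p53 (without a source for each gene), mevalonate and sterol synthesis, proteasome subunits, G2/M genes, S phase genes, mesenchymal and matrix genes, epithelial junction genes, TGF-beta response, YAP and TEAD targets, Wnt targets, type I interferon response, NF-kB genes, unfolded protein response, ATF4 response, hypoxia and glycolysis, NRF2 targets, heat shock response, nuclear-encoded oxidative phosphorylation genes, mitochondrially encoded genes, ribosomal proteins, histones, and markers of gastric differentiation, blood cells, endothelium and HEK293 or neural cells. Lists with at least 5 tested members were tested by camera with a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists of a comparison. Some genes belong to more than 1 list, for example SLC7A11 to those of ATF4, NRF2 and mutant p53, and SESN2 to those of p53 activated targets and ATF4.

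Named genes were, among called genes with a mean CPM of at least 1 and libraries that did not overlap between sides, the 10 with the largest rise and the 10 with the largest fall against GFP, or 5 and 5 between mutants. Up to 4 members of each list with the lowest p were also named, and genes with antisense, readthrough or placeholder names were passed over. Results for 1 gene that the rule also took are left out.

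The alternatives were DESeq2's size factors, library size alone, no filter beyond 1 count, a mean CPM of at least 1, DESeq2 1.42.0, limma-voom 3.58.1, only the groups compared, a replicate block, leaving out each library in turn, a log2 fold change of at least 1, an estimated correlation in camera, and fry. A correction for transcript length, thinning to the depth of the shallowest library, and the length correction without GFP replicate 1 were chosen after seeing the data. Transcript lengths came from GENCODE 29, matched by symbol, and covered 97.4% of tested genes. The correction fitted a loess (span 0.3) of each gene's deviation from its mean log2 CPM on log2 length in each library, over genes with a log2 CPM above 3, and entered the fit as an offset.

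Agreement between mutants was set against 20 data sets simulated from a negative binomial model without any change, with the same shared GFP libraries. The procedure was tested on simulated data of 13095 genes with 200 changed: 85% of genes changed 2-fold and 72% of those changed 1.5-fold were recovered, 9 of 166 calls were false, and an unchanged comparison gave 0 calls. With a simulated length trend in GFP replicate 1, 14 of 174 calls were false without the correction and 6 of 170 with it. Apart from that trend every simulated group had the same spread, whereas the real GFP libraries differed more than those of any mutant. The counts of false calls may therefore be too low for the real comparisons with GFP. A simulated list of 30 genes raised 1.3-fold gave a camera adjusted p = 1.3e-27, and 1 of 25 unchanged lists was called. No correlation between the members of a list was simulated. This simulation therefore cannot show how often camera with the preset correlation calls lists whose members vary together. In the data 16 of 50 list calls were kept with an estimated correlation. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.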

Results

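HGC27 is an established human gastric carcinoma line, and the labels describe the cells used here as lacking p53. The cells overexpressed GFP, as the control, or 1 of 3 p53 proteins with a substitution in the DNA-binding domain. R175H disturbs the fold of that domain, whereas R248Q and R273H replace residues that touch DNA. Each of the 4 groups had 2 libraries, and the values are read counts per gene from mRNA sequencing. Total counts were 9769342 and 8928928 in GFP, 6800463 and 9017777 in R175H, 11659301 and 11599907 in R248Q and 11287251 and 11788035 in R273H. Of 25435 genes in the table, 13213 passed the count filter and held 99.9% of all counts. The labels number the libraries of a group without saying whether they came from separate cultures. The p-value of a single gene therefore measures only the spread between these libraries. In the main fit that spread was pooled over all 8 libraries. Camera's p-value for a list also sets its members against the other genes. It thus depends on the number of genes and on the correlation assumed between them. With that correlation estimated, 16 of 50 list calls were kept.

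Genes that wild-type p53 is known to activate were not set apart from the other genes as a list in any mutant. Of 34 tested members, R175H had 3 called higher and 3 lower (also 3 and 3 adjusted over the list alone), with a median log2 fold change of 0.04. Among them PLK2, a stress-responsive kinase, reached 0.53 ± 0.06, GDF15, a secreted stress cytokine, 1.5 ± 0.26, SESN2, which restrains mTORC1, 0.64 ± 0.10, and AEN, a nuclease, -0.48 ± 0.09 (SE, n = 2 per group). R248Q had 1 higher and 1 lower (1 and 0 over the list alone, median -0.06). R273H had SESN2 alone (0.43 ± 0.10, SE, also 1 over the list alone, median -0.04), a gene that is in the ATF4 list as well. Set against the other genes by camera, the list of p53 targets was past no threshold (adjusted p = 0.68 in R175H, 0.36 in R248Q and 0.59 in R273H). In R175H fry, which asks only whether the members move one way, did pass (adjusted p = 0.015, upward). The SESN2 call in R273H was lost without GFP replicate 1 (0.27), R273H replicate 1 (0.46) or R273H replicate 2 (0.41), and without any 1 library of R175H or R248Q (0.43 each time).

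The 2 GFP libraries differed from each other more than the libraries of any mutant group, and the difference followed transcript length. Over replicate pairs, chi-square per degree of freedom was 5.72 in GFP, 1.6 in R175H, 1.21 in R248Q and 1.51 in R273H. Because the main fit pooled the spread, comparisons with GFP met a smaller spread than that between the GFP libraries. Pairs of mutants met a larger one than their own. GFP replicate 1 had fewer counts than its peers in long transcripts and more in short ones: for the 917 well-counted genes with transcripts of 8000 nt or more its median deviation was -0.28 (log2), against -0.03 in GFP replicate 2. Both R248Q libraries deviated the other way, by 0.14 and 0.13. Length explained 34.6% of the variance of the difference between the GFP libraries across genes. Against the mean of both GFP libraries these 917 genes had a median log2 fold change of 0.17 in R175H, 0.29 in R248Q and 0.15 in R273H. Against GFP replicate 2 alone the medians were 0.05, 0.15 and 0.04.

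**Figure D1:**
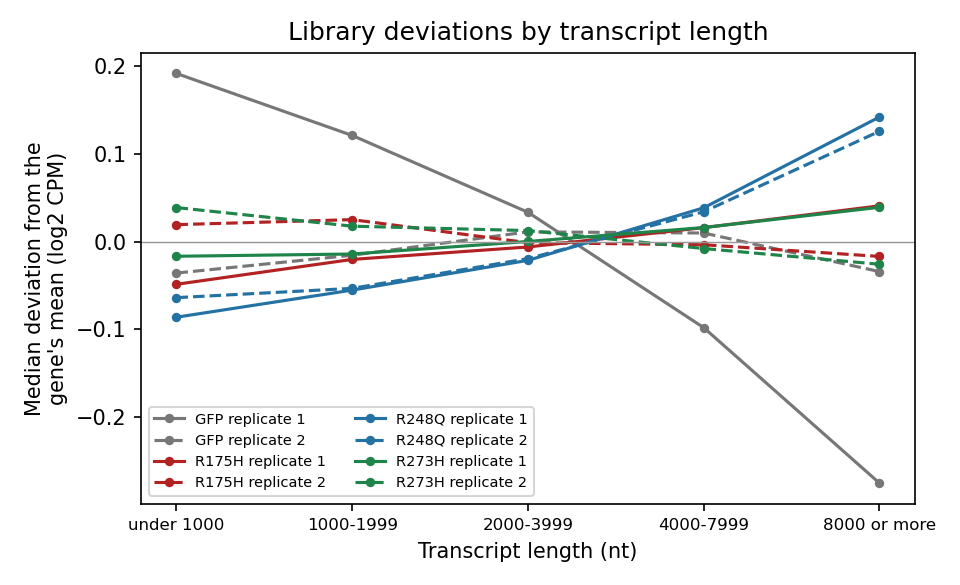
Median deviation of each library from the gene's mean over all 8 libraries (vertical axis, log2 CPM) by transcript length (horizontal axis, nt); each line is a library, dashed for replicate 2. GFP replicate 1 ran from 0.19 under 1000 nt to -0.28 at 8000 nt or more, and the R248Q libraries reached 0.14 and 0.13 there.

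The comparison of R175H with GFP asks what this mutant changes in cells described as lacking p53. Genes that respond to low oxygen rose together. NDRG1, a hypoxia-induced growth regulator, went from 10.2 ± 0.62 to 44.9 ± 0.53 CPM (counts scaled to a common library total, SD, n = 2 per group), a log2 fold change of 2.14 ± 0.12 (SE). Its adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 1.5e-08. CA9, which encodes carbonic anhydrase 9, rose by 1.84 ± 0.13, MIR210HG, the host transcript of a hypoxia-induced microRNA, by 2.05 ± 0.17, and NDUFA4L2, a HIF target in mitochondria, by 1.79 ± 0.08 (log2, SE). Of 33 tested members of the hypoxia and glycolysis list, 28 rose and none was called lower (32 and 0 adjusted over the list alone), with a median log2 fold change of 0.70 (camera adjusted p = 5.5e-26, adjusted p = 0.0040 with an estimated correlation). Its members included the glucose transporter SLC2A1 (1.03 ± 0.06), PDK1, which keeps pyruvate out of mitochondria (1.49 ± 0.10), and the mitophagy receptor BNIP3L (1.16 ± 0.07, SE). R175H replicate 1 had the lowest total of all libraries, 6800463 counts.

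Genes of the amino acid stress response driven by ATF4 also rose in R175H. Of 33 tested members 30 rose (31 adjusted over the list alone) and none was called lower, with a median log2 fold change of 0.45 (camera adjusted p = 2.4e-21, adjusted p = 0.0040 with an estimated correlation). DDIT4, an inhibitor of mTORC1 that hypoxia also induces, rose by 1.45 ± 0.05, the pseudokinase TRIB3 by 0.77 ± 0.07, PCK2 by 0.76 ± 0.07 and the transaminase GPT2 by 0.62 ± 0.06 (log2, SE, n = 2 per group). Of 25 genes of mevalonate and sterol synthesis 13 rose (13 over the list alone), among them INSIG1 (0.61 ± 0.05), HMGCS1 (0.53 ± 0.05), MSMO1 (0.53 ± 0.07) and SQLE (0.43 ± 0.05, SE). The list's median was 0.26 (camera adjusted p = 5.2e-07, adjusted p = 0.030 with an estimated correlation).

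Chaperone genes fell in R175H. Of 24 heat shock genes 16 fell (19 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 5.0e-13, adjusted p = 0.047 with an estimated correlation). The HSP70 family member HSPA8 fell by 0.61, its partner DNAJA1 by 0.66, HSPH1 by 0.63 and HSP90AA1 by 0.42 on the log2 scale. HSPA1A and HSPA1B are near-identical copies, so their separate values are uncertain. In the endoplasmic reticulum, the chaperones HSPA5 (-0.53 ± 0.05), HSP90B1 (-0.41 ± 0.06) and CALR (-0.35 ± 0.05) and the secreted factor MANF (-0.65 ± 0.08, SE) fell. Of 24 members of the unfolded protein response list 11 fell and 3 rose (12 and 3 over the list alone, median -0.20, camera adjusted p = 0.0079), and adjusted p = 0.39 with an estimated correlation. Of 31 proteasome subunits 7 fell (16 over the list alone), PSMD12 by 0.39 (log2), and the list's median was -0.17 (camera adjusted p = 9.5e-08, adjusted p = 0.39 with an estimated correlation). Both medians were nearer 0 without GFP replicate 1, -0.10 for the proteasome (camera adjusted p = 0.0013) and -0.13 for the unfolded protein response (camera adjusted p = 0.025).

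Genes of cell division were slightly lower in R175H. Of 32 G2/M genes 12 fell (14 adjusted over the list alone), with a median log2 fold change of -0.14 (camera adjusted p = 7.4e-06, adjusted p = 0.030 with an estimated correlation). The mitotic cyclin CCNB1 had -0.29 ± 0.05, the APC/C activator CDC20 -0.28 ± 0.05, AURKA -0.35 ± 0.07 and BIRC5 -0.30 ± 0.06 (SE). The last 3 of these calls were lost without R175H replicate 1, the library with the lowest total count (CDC20 -0.26, AURKA -0.30 and BIRC5 -0.27). Of 39 S phase genes 5 fell and 1 rose (9 and 1 over the list alone, median -0.11, camera adjusted p = 1.5e-04, adjusted p = 0.0496 with an estimated correlation), with the nuclease FEN1 at -0.39 ± 0.06, ORC6 at -0.46 ± 0.09 and the licensing factor CDT1, which rose, at 0.34 ± 0.06 (SE).

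Among single genes, TXNIP, which restrains glucose uptake, fell in R175H by 2.25 (log2, 31.6 ± 1.4 to 6.58 ± 0.54 CPM, SD, n = 2 per group, edgeR adjusted p = 4.7e-08), and the small heat shock protein CRYAB fell by 1.27. TXNIP is a member of a list of 25 tested genes set down as induced by mutant p53, of which 10 rose and 3 fell (10 and 6 over the list alone). No source was recorded for its single members, so a rise of one is not taken as agreement with an earlier report. The list's median was 0.24 and its camera adjusted p = 0.44, with the cystine transporter SLC7A11 at 0.75 ± 0.07 and IGF1R at 0.58 ± 0.11 (SE). KIAA1244 (2.87 ± 0.50) and RIMKLA (2.14 ± 0.34, SE) rose from few counts. Of 29 mesenchymal and matrix genes 7 rose and 4 fell (10 and 5 over the list alone, median 0.07, camera adjusted p = 0.75), the collagen crosslinkers LOX at 0.59 ± 0.08 and LOXL2 at 0.61 ± 0.07, the repressor TWIST1 at 0.44 ± 0.06 and THY1 at -0.59 ± 0.09 (SE).

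In all, edgeR called 844 genes higher and 607 lower in R175H than in GFP, of which 49 and 24 changed at least 2-fold. Long transcripts were frequent among the higher genes: their median length was 4965 nt, against 2576 nt for the lower ones and 3390 nt for all genes tested. With the length trend removed the counts were 1065 and 1063. Without R175H replicate 1 they were 309 and 154, without R175H replicate 2 344 and 180, and without GFP replicate 2 1846 and 1546. Without R248Q replicate 1 or 2, 400 and 396 genes were lower. Of 85 named calls in this comparison 32 were lost without R175H replicate 1 and 24 without R175H replicate 2. The calls of NDRG1, CA9, MIR210HG, NDUFA4L2, KIAA1244, RIMKLA, TXNIP and CRYAB held under every alternative with the same threshold in which they were tested.

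**Figure D2:**
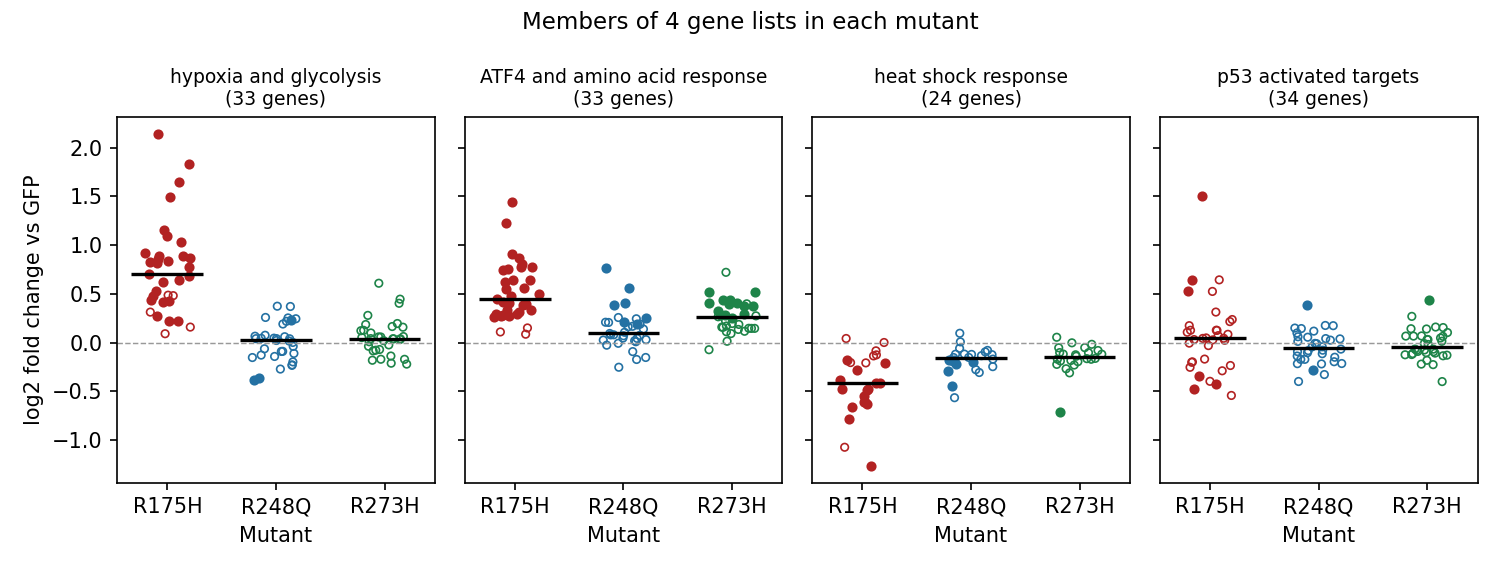
Log2 fold change against GFP (vertical axis) of each tested member of 4 gene lists in each mutant; filled points passed edgeR's test (adjusted p below 0.05), open points did not, and black lines are medians. In R175H the median of the hypoxia list was 0.70 and that of the heat shock list -0.42.

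R248Q was compared with GFP in the same way. The stromal Wnt antagonist SFRP4 fell by 1.14 (log2, 78.9 ± 1.7 to 35.7 ± 1.9 CPM, SD, n = 2 per group, edgeR adjusted p = 4.1e-07), and so did the contractile genes ACTA2 (-1.20 ± 0.11) and TAGLN (-1.06 ± 0.13, SE). Genes with very long transcripts rose, among them SYNE2, a giant nuclear envelope protein (1.75 ± 0.11), the laminin LAMA1 (1.49 ± 0.17), the protocadherin FAT4 (1.38 ± 0.14) and the histone methyltransferases KMT2D (1.27 ± 0.11) and KMT2A (1.23 ± 0.13, SE). The matrix genes POSTN (0.43 ± 0.05) and COL1A1 (0.37 ± 0.05) and the cystine transporter SLC7A11 (0.77 ± 0.07, SE) also rose, and the transcription factor TOX3 fell by 2.28 from a few counts.

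By list, ATF4 genes rose less than in R175H: 7 of 33 rose (12 higher and 1 lower adjusted over the list alone), with a median of 0.09 (camera adjusted p = 4.4e-04, adjusted p = 0.24 with an estimated correlation), led by SLC7A11 and ALDH1L2 (0.56 ± 0.09, SE). Of 24 heat shock genes 7 fell (11 over the list alone, median -0.16, camera adjusted p = 2.8e-06), and adjusted p = 0.26 with an estimated correlation. Of 31 proteasome subunits 3 fell (10 over the list alone, median -0.16, camera adjusted p = 3.4e-07), and adjusted p = 0.48 with an estimated correlation. The proteasome median was -0.09 without GFP replicate 1 (camera adjusted p = 0.0018) and -0.06, not called, with the length trend removed as well. The S phase (-0.07, camera adjusted p = 0.0053), unfolded protein response (-0.09, 0.047), oxidative phosphorylation (-0.13, 1.4e-04), ribosomal protein (-0.12, 1.7e-04) and histone (-0.24, 0.025) lists had lower medians and passed camera with few members called: 1 of 39, 4 of 24, 1 of 38, 0 of 40 and 1 of 11 lower. Over the list alone these were 0, 7, 0, 0 and 1 lower, and 1 S phase gene was higher (1 over the list alone). For the ribosomal proteins edgeR gave 10 lower at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. These 5 lists gave adjusted p = 0.26, 0.48, 0.62, 0.64 and 0.30 with an estimated correlation, and none of the 5 passed camera with the length trend removed.

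Without GFP replicate 1, 4 of these camera calls were lost in R248Q, with medians of -0.04 for the unfolded protein response, -0.02 for oxidative phosphorylation, 0.01 for ribosomal proteins and -0.18 for histones. The histone call was also lost among genes with a mean CPM of at least 1 (median -0.09), and its median was -0.43 without R248Q replicate 1. The S phase call was also lost without R248Q replicate 2 (median -0.07), and the unfolded protein response call without any 1 library other than GFP replicate 2 (medians -0.09 to -0.04) and among genes with a mean CPM of at least 1. In the hypoxia list, 1 of 33 members rose and 2 fell (1 and 2 over the list alone, median 0.02, camera adjusted p = 0.83), with the hexokinase HK1 at -0.36 ± 0.07 (SE, lost without either R248Q library, -0.35 and -0.37). G2/M genes were divided: the long MKI67 (0.84 ± 0.10) and CENPF (0.53 ± 0.07) rose while CCNB1 (-0.23 ± 0.05) and BIRC5 (-0.23 ± 0.06, SE) fell, giving 2 higher and 2 lower of 32 (2 and 5 over the list alone, median -0.07, camera adjusted p = 0.16). The CCNB1 and BIRC5 calls were lost without either R248Q library (CCNB1 -0.25 and -0.21, BIRC5 -0.23 and -0.22), BIRC5 also without GFP replicate 1 (-0.16) or any 1 library of R175H or R273H (-0.23 each time).

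In all, edgeR called 645 genes higher and 190 lower in R248Q than in GFP, 52 and 16 of them at least 2-fold. Of the 645 higher genes 377 had transcripts of 8000 nt or more, and the median length was 8665.5 nt for the higher and 2188 nt for the lower genes. With the length trend removed the counts were 407 higher and 453 lower, and 170 of the 377 long and 141 of the 268 other higher genes were still called higher. Without GFP replicate 1 the counts were 424 and 155, without GFP replicate 2 1839 and 1608, without R248Q replicate 1 198 and 29, and without R248Q replicate 2 199 and 27. The lower count was 106, 106, 96 and 97 without each R175H and R273H library in turn. Of 71 named calls 49 were lost without R248Q replicate 1 and 46 without R248Q replicate 2. The calls of SYNE2, LAMA1, FAT4, KMT2D, KMT2A, SLC7A11, ALDH1L2, SFRP4, ACTA2, TAGLN, POSTN, COL1A1, TOX3, MKI67 and CENPF held under every alternative with the same threshold.

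R273H differed least from GFP. As in R248Q, SFRP4 fell by 1.15 (log2, 78.9 ± 1.7 to 35.7 ± 0.025 CPM, SD, n = 2 per group, edgeR adjusted p = 8.3e-07) together with ACTA2 (-1.04 ± 0.10) and TAGLN (-0.88 ± 0.12), and the endocytic receptor LRP2 fell by 1.09 and the chemokine CCL2 by 1.29. LAMA1 (1.03 ± 0.18), FAT4 (0.78 ± 0.14), SYNE2 (0.75 ± 0.12) and the ankyrin ANK2 (0.78 ± 0.11, SE) rose, all with transcripts of 8000 nt or more, as did POSTN (0.40 ± 0.05) and COL1A1 (0.35 ± 0.05, SE). Of 33 ATF4 genes 13 rose (25 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 4.1e-18, adjusted p = 0.011 with an estimated correlation), among them DDIT4 (0.37 ± 0.05), SLC7A11 (0.52 ± 0.07), GPT2 (0.40 ± 0.06) and CHAC1, which degrades glutathione (0.52 ± 0.08, SE). Calls lost with 1 R273H library left out were TAGLN -0.80 without R273H replicate 1, LRP2 -0.91 without R273H replicate 2, CCL2 -0.99 without R273H replicate 1, LAMA1 0.95 without R273H replicate 1 and 1.11 without R273H replicate 2, FAT4 0.62 without R273H replicate 1, SYNE2 0.62 without R273H replicate 1, ANK2 0.77 without R273H replicate 1, POSTN 0.40 without R273H replicate 1, COL1A1 0.34 without R273H replicate 1 and 0.36 without R273H replicate 2, DDIT4 0.33 without R273H replicate 2, SLC7A11 0.50 without R273H replicate 1, GPT2 0.43 without R273H replicate 1 and 0.38 without R273H replicate 2, CHAC1 0.53 without R273H replicate 1 and 0.52 without R273H replicate 2.

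Of 24 heat shock genes in R273H 1, CRYAB, fell (-0.71 ± 0.13, SE, call lost, -0.63 without R273H replicate 1 and -0.80 without R273H replicate 2, 9 over the list alone, median -0.15, camera adjusted p = 6.7e-07), and adjusted p = 0.20 with an estimated correlation. The mevalonate list had 0 of 25 members called (7 higher over the list alone, 9 higher at an unadjusted p under 0.05, 0 by DESeq2 and 3 by limma-voom, median 0.11, camera adjusted p = 9.9e-04), and adjusted p = 0.17 with an estimated correlation. Proteasome, interferon and oxidative phosphorylation genes had 0 called over all genes and over the list alone by edgeR and 0 by DESeq2 and limma-voom, and 6, 5 and 3 lower at an unadjusted p under 0.05. Their medians were -0.09, -0.07 and -0.07, with camera adjusted p = 2.4e-04, 0.023 and 0.023, and adjusted p = 0.58, 0.20 and 0.72 with an estimated correlation. Without GFP replicate 1 the proteasome median was -0.01 and the oxidative phosphorylation median 0.04, with neither called. The mevalonate (0.11) and interferon (-0.03) calls were lost without GFP replicate 2. The interferon median was -0.14 without GFP replicate 1 and -0.17 without R273H replicate 2, and the proteasome median -0.05 without R273H replicate 1. The interferon (-0.07) and oxidative phosphorylation (-0.05) calls were lost without R273H replicate 1. The hypoxia list had 0 of 33 called (1 higher over the list alone, 5 higher and 2 lower at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom, median 0.04, camera adjusted p = 0.29).

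In all, edgeR called 100 genes higher and 33 lower in R273H than in GFP, 2 and 8 of them at least 2-fold. Of the 100 higher genes 64 had transcripts of 8000 nt or more. With the length trend removed the counts were 188 and 133. Without R273H replicate 1 they were 2 and 6, without R273H replicate 2 16 and 7, and without GFP replicate 2 1327 and 931. Without GFP replicate 1, 62 genes were lower. Without each R175H and R248Q library in turn 44, 44, 45 and 45 genes were higher and 20 were lower in each case, and with only the groups compared 1 was higher and 5 were lower. Of 31 named calls 27 were lost without R273H replicate 1 and 21 without R273H replicate 2. The calls of SFRP4 and ACTA2 held under every alternative with the same threshold.

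The mean of the 3 mutants against GFP asks what they change on average. DDIT4 rose by 0.67 ± 0.04 and SLC7A11 by 0.68 ± 0.06, whereas TXNIP (-1.12 ± 0.09), ACTA2 (-0.95 ± 0.08) and TAGLN (-0.87 ± 0.10, log2, SE) fell. SLAIN1, a microtubule regulator, rose by 1.22 ± 0.20 and SYNE2 by 1.11 ± 0.10 (SE). Of 33 ATF4 genes 22 rose (28 adjusted over the list alone, median 0.24, camera adjusted p = 1.6e-17, adjusted p = 0.011 with an estimated correlation). Of 33 hypoxia genes 20 rose (22 higher and 1 lower over the list alone, median 0.30, camera adjusted p = 1.9e-11, adjusted p = 0.017 with an estimated correlation), a mean to which R248Q and R273H added medians of 0.02 and 0.04. Of 24 heat shock genes 14 fell (20 over the list alone, median -0.25, camera adjusted p = 1.9e-11), and adjusted p = 0.074 with an estimated correlation. The proteasome (-0.14), mevalonate (0.15), S phase (-0.09), G2/M (-0.10), unfolded protein response (-0.09) and oxidative phosphorylation (-0.09) lists also passed camera in the direction of their medians, and none of these 6 passed with an estimated correlation (adjusted p = 0.39, 0.072, 0.086, 0.093, 0.39 and 0.64). Leaving out GFP replicate 1 gave medians of 0.03 for oxidative phosphorylation, -0.07 for the proteasome, -0.06 for S phase and -0.05 for the unfolded protein response, the last 3 still called.

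In all, edgeR called 689 genes higher and 402 lower in the mean of the mutants, 14 and 12 of them at least 2-fold, and 312 of the higher genes had transcripts of 8000 nt or more. Of 78 named calls 13 were lost with the replicate block, and more without any 1 library other than GFP replicate 2. With the length trend removed the counts of higher and lower genes were 669 and 757. Without GFP replicate 1 they were 370 and 221, without GFP replicate 2 1881 and 1599, without R175H replicate 1 392 and 177, without R248Q replicate 1 371 and 141, without R248Q replicate 2 377 and 144, and without R273H replicate 1 379 and 148. Without R175H replicate 2 and R273H replicate 2, 218 and 202 genes were lower.

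Genes called in more than 1 mutant moved the same way with few exceptions. R175H and R248Q shared 247 higher and 79 lower genes, with 7 called in opposite directions, where lists drawn independently would share 41.2 and 8.73. R175H and R273H shared 87 and 14 (6.39 and 1.52 if independent), and R248Q and R273H shared 89 and 29 (4.88 and 0.475 if independent), with 0 opposite calls in both pairs. In all 3 mutants 77 genes were higher and 14 lower. The lower genes included SFRP4, ACTA2, TAGLN, the light chain gene MYL9, TXNIP, CRYAB, the growth factor binding protein gene IGFBP3, the TGF-beta pseudoreceptor gene BAMBI and the homeobox gene MSX2; MYL9 and MSX2 were named after their values were seen. Most of the 77 higher genes had transcripts of 8000 nt or more, SYNE2, FAT4, KMT2A and LAMA1 among them. Of the 13213 genes tested 1096 were that long. At these lengths GFP replicate 1 had fewer counts than its peers.

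All 3 comparisons use the same 2 GFP libraries, which by itself makes their fold changes move together. In 20 simulated data sets without any change, in which the groups shared controls in the same way, the mean correlation across 10017 genes was 0.499 for R175H and R248Q, 0.497 for R175H and R273H and 0.530 for R248Q and R273H, against 0.563, 0.621 and 0.809 in the data. Genes are not independent replicates. The covariances were 0.0260, 0.0211 and 0.0252 against simulated means of 0.00579, 0.00576 and 0.00580. Part of the excess may still come from the shared controls, since GFP replicate 1 deviated with transcript length and the GFP replicates differed more than those of the mutants, which the simulation left out. With the length trend removed the correlations were 0.499, 0.569 and 0.765, for R175H and R248Q no higher than in the simulation. Changes particular to 1 mutant also lower a correlation, so this value cannot show that the pair shared nothing, and covariances were not compared there. R175H and R248Q then shared 179 higher and 224 lower genes, called against the same GFP libraries. In all 3 mutants 97 genes were then higher and 64 lower. Without GFP replicate 1, 25 genes were lower in all 3, and 9 of the 14 were still among the lower ones. Without GFP replicate 2 there were 916 higher and 648 lower, with 13 of the 14 still lower. Without R175H replicates 1 and 2 the shared counts were 19 and 24 higher and 8 and 6 lower, without those of R248Q 32 and 30 higher and 6 and 5 lower, and without those of R273H 0 and 14 higher and 2 and 4 lower.

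Between mutants, R175H stood apart from both others. Against R175H, R248Q had lower NDUFA4L2 (-1.87 ± 0.08), CA9 (-1.93 ± 0.13), MIR210HG (-1.90 ± 0.16) and APLN, which encodes the vascular peptide apelin (-1.80 ± 0.14), and higher TXNIP (1.69 ± 0.14) and the glutamate receptor gene GRIK3 (1.51 ± 0.22, log2, SE, n = 2 per group). Of 33 hypoxia genes 30 were lower in R248Q (30 adjusted over the list alone, median -0.71, camera adjusted p = 5.7e-33, adjusted p = 0.0039 with an estimated correlation). Of 33 ATF4 genes 22 were lower (25 over the list alone, median -0.31, camera adjusted p = 1.1e-16, adjusted p = 0.0065 with an estimated correlation), and of 25 mevalonate genes 6 (13 over the list alone, median -0.16, camera adjusted p = 4.0e-07, adjusted p = 0.032 with an estimated correlation). Heat shock genes were higher in R248Q (10 of 24, 13 over the list alone, median 0.21, camera adjusted p = 4.0e-07), and adjusted p = 0.14 with an estimated correlation. So were G2/M genes (5 of 32, 6 over the list alone, median 0.11, camera adjusted p = 2.0e-04), and adjusted p = 0.053 with an estimated correlation. Ribosomal proteins were lower (3 of 40, 3 over the list alone, median -0.11, camera adjusted p = 2.0e-04), with adjusted p = 0.69 with an estimated correlation and no camera call without R175H replicate 2 (-0.07). POSTN (0.51 ± 0.05) and COL1A1 (0.49 ± 0.05) were higher and LOX (-0.50 ± 0.07, SE) lower in R248Q.

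R273H against R175H gave a like picture: NDRG1 (-1.86 ± 0.11), CA9 (-2.05 ± 0.13) and NDUFA4L2 (-1.87 ± 0.08) were lower and TXNIP (1.69 ± 0.14, SE) higher in R273H. Of 33 hypoxia genes 28 were lower (30 adjusted over the list alone, median -0.69, camera adjusted p = 7.4e-32, adjusted p = 0.0042 with an estimated correlation), and of 33 ATF4 genes 11 (20 over the list alone, median -0.21, camera adjusted p = 5.1e-11, adjusted p = 0.015 with an estimated correlation). G2/M genes were higher (2 of 32, 12 over the list alone, median 0.17, camera adjusted p = 5.0e-07, adjusted p = 0.026 with an estimated correlation). Heat shock genes were higher (10 of 24, 13 over the list alone, median 0.24, camera adjusted p = 5.0e-10), HSPA8 by 0.44 ± 0.05, and mevalonate genes lower (6 of 25, 7 over the list alone, median -0.11, camera adjusted p = 7.1e-05). For these lists adjusted p = 0.075 and 0.053 with an estimated correlation. The proteasome (1 of 31 higher, 1 over the list alone, 0.08), S phase (2 of 39 higher and 1 lower, 2 and 1 over the list alone, 0.07) and unfolded protein response (4 of 24 higher and 1 lower, 7 and 2 over the list alone, 0.13) lists passed camera (adjusted p = 0.0011, 0.0011 and 0.042), and adjusted p = 0.75, 0.077 and 0.60 with an estimated correlation. The unfolded protein response call was lost without R175H replicate 1 (0.09), either R248Q library (0.13 and 0.13) or either R273H library (0.16 and 0.10).

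R273H and R248Q differed in 20 genes, of which 19 were lower in R273H and had transcripts of 8000 nt or more. SYNE2 (-1.0 ± 0.10), the fibrillin FBN2 (-0.68 ± 0.08), UBR4 (-0.67 ± 0.10), FAT1 (-0.66 ± 0.12) and AHNAK (-0.62 ± 0.10, log2, SE, n = 2 per group) were lower, and SNTB1 (0.60 ± 0.09, SE) was the 1 higher gene. SYNE2 was not called without R273H replicate 2 (-0.88), and FBN2, UBR4, FAT1, AHNAK and SNTB1 were lost without any 1 library of the compared groups: FBN2 -0.70 to -0.66, UBR4 -0.69 to -0.66, FAT1 -0.76 to -0.57, AHNAK -0.70 to -0.54, SNTB1 0.53 to 0.66. The ATF4 list was higher in R273H, with 0 of 33 members called by edgeR, DESeq2 or limma-voom but 15 higher and 1 lower at an unadjusted p under 0.05 (9 and 1 adjusted over the list alone, median 0.12, camera adjusted p = 4.0e-09, adjusted p = 0.041 with an estimated correlation). Ribosomal protein, proteasome, oxidative phosphorylation and hypoxia lists had medians of 0.10, 0.07, 0.06 and 0.07 and passed camera (adjusted p = 1.0e-05, 0.0028, 0.014 and 0.030), and adjusted p = 0.72, 0.72, 0.79 and 0.36 with an estimated correlation. In these 4 lists edgeR, DESeq2 and limma-voom called 0 members, also 0 over the list alone, and 5, 1, 1 and 1 were higher at an unadjusted p under 0.05. The proteasome (0.04) and oxidative phosphorylation (0.03) calls were lost without R273H replicate 2, the latter also without R248Q replicate 1 (0.05). The hypoxia call was lost without R248Q replicate 1 (0.07) or either R273H library (0.05 and 0.07).

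In all, edgeR called 947 genes between R248Q and R175H (425 higher and 522 lower in R248Q), 479 between R273H and R175H (186 and 293) and 20 between R273H and R248Q, with 60, 37 and 0 at least 2-fold. With the replicate block, the named calls lost were 15 of 67, 11 of 54 and 5 of 7, in the same order. More were lost without any 1 library of the compared groups. With the length trend removed the counts of genes called were 1562, 1095 and 60. Leaving out GFP replicate 1, which these comparisons do not use except for the spread, gave 2430, 1640 and 574 genes, and leaving out GFP replicate 2 gave 2435, 1631 and 573. Leaving out each library of the compared groups in turn gave 231 to 335 genes for R248Q against R175H, 117 to 147 for R273H against R175H and 0 to 1 for R273H against R248Q, the 0 without R273H replicate 2. Without either library of R248Q the count for R273H against R175H was 298 and 296, and without either library of R175H the count for R273H against R248Q was 4.

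The remaining lists passed no camera threshold in R175H, R248Q or R273H against GFP. In that order of mutants, members called higher and lower were 3 and 0, 1 and 0, and 0 and 0 of 17 epithelial junction genes, 2 and 6, 0 and 1, and 0 and 1 of 22 TGF-beta genes, and 2 and 1, 5 and 1, and 0 and 1 of 22 YAP and TEAD targets. They were 4 and 1, 0 and 1, and 0 and 0 of 18 Wnt targets, 2 and 0, 0 and 1, and 0 and 1 of 13 NF-kB genes, and 1 and 2, 1 and 0, and 1 and 0 of 22 NRF2 targets. Adjusted over the list alone, the counts were 4 and 0, 3 and 0, and 0 and 0 for epithelial genes, 3 and 6, 0 and 1, and 0 and 1 for TGF-beta, 4 and 3, 6 and 1, and 3 and 1 for YAP, 5 and 1, 0 and 2, and 1 and 2 for Wnt, 2 and 0, 0 and 1, and 0 and 1 for NF-kB, and 1 and 5, 1 and 0, and 1 and 0 for NRF2. Where edgeR called 0 epithelial genes and 0 Wnt targets in R273H, 1 and 1 were higher and 0 and 3 lower at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Interferon genes had 1 of 26 lower in R175H (1 over the list alone, camera adjusted p = 0.088) and 2 lower in R248Q (4 over the list alone, camera adjusted p = 0.32). Single members moved clearly: the hypoxia-inducible repressor gene BHLHE40, in the TGF-beta list, rose by 0.98 ± 0.08 and APCDD1, a Wnt antagonist gene, fell by 0.45 in R175H. IGFBP3 fell in all 3 mutants (in R273H not called, -0.60 without R273H replicate 1 and -0.44 without R273H replicate 2), and the YAP target DOCK5 rose in R248Q (0.71 ± 0.12, SE). The keratin gene KRT8, which has many pseudogenes, rose in R248Q (1.32 ± 0.35, SE), a call lost without GFP replicate 1 (1.46), either R175H library (1.32 and 1.32) or either R248Q library (1.44 and 1.19).

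Median, mean and test differed in sign for some lists. Ribosomal proteins in R175H had a median of -0.02 and an upward camera direction (adjusted p = 0.99), with RPL3 the only member called of 40 (1 over the list alone, RPL3 0.23 without R175H replicate 1 and 0.21 without R175H replicate 2 and 0.21 without R248Q replicate 2, not called). YAP targets in R175H had a median of 0.05, a mean of -0.01 and a downward direction, and the mesenchymal list in R273H a median of 0.04, a mean of -0.03 and an upward direction. NF-kB genes in R175H had a median of -0.28, a mean of -0.23 and a downward direction (camera adjusted p = 0.12), opposite to the 2 members called higher. This list passed camera without R273H replicate 1 (-0.28) or 2 (-0.22) and with only the groups compared (-0.24). Histones in R175H had a median of 0.03 and a mean of -0.09, and the hypoxia list in R248Q pointed down in camera at a median of 0.02. Wnt targets in R248Q had a median of 0.05 and a mean of -0.02, and epithelial genes in R273H a median of -0.02 and a mean of 0.09. In R248Q and R273H 2 and 2 of 29 mesenchymal genes rose and 3 and 2 fell (2 and 2, and 3 and 3, over the list alone, camera adjusted p = 0.83 and 0.79). The mutant p53 list had 6 higher and 1 lower of 25 in R248Q (6 and 2 over the list alone, camera adjusted p = 0.12) and 5 and 1 in R273H (8 and 1, camera adjusted p = 0.066). Its members KMT2A, KMT2D, IGF1R and SLC7A11, higher in all 3 mutants, had transcripts of 16628, 19419, 12235 and 9645 nt. The GFP libraries differed from each other at such lengths. These genes were also called in all 3 with the length trend removed, but that correction takes out only the average trend. In GFP they had 61.6 ± 20.2, 95.4 ± 25.5, 31.0 ± 4.7 and 73.5 ± 6.4 CPM (SD), in the same order. The calls used the pooled spread, which was smaller than that between the GFP libraries. They therefore cannot show that KMT2A and KMT2D changed beyond the difference between the GFP libraries.

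Markers of other cell types were few. Of 27 gastric and intestinal differentiation genes listed in the table, 3 passed the count filter, with GATA6 the highest at 28.4 CPM, and GATA6 was called higher in R175H (0.41 ± 0.11, SE). This call was lost without GFP replicate 1 (0.30) or R175H replicate 1 (0.32). Of 20 blood cell markers 4 passed, the highest HBA1 at 11.4 CPM, which has a near-identical copy, and of 12 endothelial markers 4, the highest EGFL7 at 124 CPM. Of 18 markers of HEK293 or neural cells 8 passed, the highest TUBB3 at 188 CPM. TUBB3 fell in R175H (-0.38 ± 0.06) and R248Q (-0.24 ± 0.05), the adhesion gene NCAM1 rose in R175H (0.43 ± 0.08) and R248Q (0.30 ± 0.07), and CNTN1 fell in R248Q (-0.42 ± 0.06) and R273H (-0.37 ± 0.06, SE). Not called with 1 library left out were TUBB3 -0.25 without R248Q replicate 1 and -0.23 without R248Q replicate 2, NCAM1 0.22 without GFP replicate 1 and 0.32 without R248Q replicate 1 and 0.29 without R248Q replicate 2 in R248Q and CNTN1 -0.37 without R273H replicate 1 and -0.37 without R273H replicate 2 in R273H. The list of 8 had 1 higher and 1 lower in R175H (1 and 1 over the list alone, median -0.05, camera adjusted p = 0.80) and 1 higher and 2 lower in R248Q (1 and 2, median 0.23, 0.83). In R273H edgeR called 0 higher and 1 lower (1 and 1 over the list alone, 1 and 3 at an unadjusted p under 0.05, 0 and 1 by DESeq2 and limma-voom, median -0.04, camera adjusted p = 0.40). The blood and endothelial markers had 0 members called by edgeR, DESeq2 or limma-voom in each mutant against GFP, with 2 blood markers lower in R248Q at an unadjusted p under 0.05 and over the list alone. The table held none of the genes encoded by the mitochondrial genome, so their share could not be used as a sign of RNA quality.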

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

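The differences between mutants below came from comparisons set before the data were examined, but the tests weighing explanations of the hypoxia pattern (thinning, length correction, and the gap between libraries) were chosen after the result was seen.

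List medians differed between mutants, each by camera on the difference itself, with 2 libraries per group. Against R175H, R248Q had lower medians in the hypoxia and glycolysis (-0.71, log2), ATF4 (-0.31) and mevalonate (-0.16) lists, with camera adjusted p = 5.7e-33, 1.1e-16 and 4.0e-07. Against R175H, R273H had lower medians in the hypoxia (-0.69) and ATF4 (-0.21) lists and a higher one in the G2/M list (0.17), with camera adjusted p = 7.4e-32, 5.1e-11 and 5.0e-07. R273H had a higher ATF4 median than R248Q (0.12; camera adjusted p = 4.0e-09). These 7 differences were chosen because they passed camera with both the preset and an estimated correlation, so passing the second is no further support. Differences between mutants that passed only with the preset correlation are left out of this paragraph.

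The hypoxia and glycolysis list was higher in both R175H libraries, by medians of 0.68 and 0.71 (log2) over the GFP mean, than in the other 6, where it was at most 0.05. A difference in depth between the libraries is argued against: of the 2 R175H libraries only replicate 1 was shallower than both of GFP. R175H replicate 2, with the median of 0.71, had 9017777 counts, between the 8928928 and 9769342 of GFP. After thinning every library to the shallowest the median was 0.77 and 27 of 33 members were called. Thinning leaves the expected ratios of well-counted genes unchanged, so that median could not decide the question. The transcript length trend is argued against as well, since the median was 0.75 after the length correction. An effect of R175H and a difference in oxygen, density or medium of the R175H cultures cannot be told apart: the lowest R175H library lay 0.63 above the highest of the other 6, which either may give, and the labels give no separate cultures. That R175H raises these genes is thus a hypothesis, for which independent cultures grown side by side would be a test.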

How the results depend on the processing

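The length correction, thinning, and the length correction without GFP replicate 1 were chosen after seeing the data; the other alternatives were planned. Where 1 library of a group was left out, the lone library was assumed to vary like the other groups. DESeq2 was not used for list tests, and only the groups compared was not possible for the mean of the 3 mutants. Except where stated, the cause of a change was not tested.

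In R175H the hypoxia, ATF4, heat shock, mevalonate, G2/M and S phase lists kept their call in all 20 alternatives, with medians of 0.66 to 0.77 for hypoxia, 0.43 to 0.49 for ATF4, -0.45 to -0.34 for heat shock and 0.19 to 0.30 for mevalonate. So did ATF4 in R273H (0.20 to 0.27). Of 50 list calls, 50 were kept with either other scaling, 46 without a filter, 49 with the replicate block and thinned, 41 with the length correction, 32 by fry and 16 with an estimated correlation.

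Genes higher and lower by DESeq2 were 490 and 337 in R175H, 416 and 66 in R248Q and 449 and 163 in the mean, with 20 lower in R273H, 534 between R248Q and R175H, 285 between R273H and R175H, and 50 higher and 6 lower in all 3. With only the groups compared, 2 residual degrees of freedom and the spread of those groups alone remain. Genes higher and lower were then 351 and 187 in R175H, 327 and 64 in R248Q and 1 and 5 in R273H, and 0 and 3 in all 3. Between mutants 2573, 1354 and 816 were called (R248Q against R175H, R273H against R175H, R273H against R248Q). A log2 fold change of at least 1, a stricter threshold by construction, gave 49 and 24, 52 and 16, 2 and 8 and, in the mean, 14 and 12, and 60, 37 and 0 between mutants; edgeR had 1065 between R273H and R248Q at an unadjusted p under 0.05. Without a filter they were 991 and 448 in R248Q, 396 and 107 in R273H and 1055 and 626 in the mean, 759 and 176 between R273H and R175H or R248Q, and 252 and 44 in all 3. With the replicate block, 96 were lower in R248Q, 38 higher and 20 lower in R273H, 458 and 213 in the mean, 318 and 4 differed between R273H and R175H or R248Q, and 27 were higher in all 3.

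With the length correction, 1063 were lower in R175H, 407 higher and 453 lower in R248Q, 188 and 133 in R273H and 757 lower in the mean, 1562, 1095 and 60 differed between mutants, 64 were lower in all 3, and 4 lists were called in R248Q and 3 in R273H against R248Q. The ribosomal protein median reversed to 0.0062 in R248Q and 0.026 in R273H. With the length correction and GFP replicate 1 left out, 266 were higher in R248Q, 193 higher and 95 lower in R273H and 409 higher in the mean, 2405, 1931 and 324 differed between mutants, 34 were lower in all 3, and 4 and 2 lists were called in R248Q and in R273H against R248Q. Medians then reversed to 0.0023, 0.012 and 0.014 for oxidative phosphorylation in R248Q, R273H and the mean, and to 0.044, 0.070 and 0.068 for ribosomal proteins. Thinned, 9 were lower in all 3.

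With an estimated correlation 0 of 8 lists were called in R248Q, 1 of 6 in R273H, 2 of 9 in the mean, and 3, 3 and 1 between mutants, of 6, 8 and 5. By fry 4 were called in R248Q, 3 in R273H and 1 in R273H against R248Q.

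Leaving out 1 library at a time gave ranges. In R175H, 309 to 1846 genes were higher and 154 to 1546 lower, in R248Q 198 to 1839 and 27 to 1608, in R273H 2 to 1327 and 6 to 931, and in the mean 370 to 1881 and 141 to 1599. Between mutants 231 to 2435, 117 to 1640 and 0 to 574 differed (the 0 by edgeR without R273H replicate 2), and in all 3 mutants 0 to 916 were higher and 2 to 648 lower. Lists called were 4 to 9 in R248Q and 2 to 7 in R273H against R248Q. Ribosomal protein medians were -0.13 to 0.12 in R175H, -0.24 to 0.0072 in R248Q, -0.14 to 0.10 in R273H and -0.17 to 0.074 in the mean, and oxidative phosphorylation -0.18 to 0.039 in R273H and -0.19 to 0.027 in the mean. Each of these lowest medians came without GFP replicate 2 and each highest without GFP replicate 1, so the sign rested on the GFP library left out. The highest counts against GFP came without GFP replicate 2, which leaves GFP replicate 1 as the only control. Depth limits the genes with few counts: 3 counts were 0.307 CPM in GFP replicate 1.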

Other observations

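The tests on long transcripts, on the GFP library left out and on the state of the GFP cultures, and the gene families, were chosen after the result was seen. A planned simulation of shared GFP libraries is not used here, since the count of shared calls it gave was fixed in advance, and the test that replaced it was divided in 2 after its result was seen. For GFP replicate 1 as the only source, R248Q minus GFP replicate 2 (median 0.15) was used at first and replaced by a comparison without any GFP library, and the bounds were changed with it; both gave the same reading. The tests for an effect of R248Q, for oxygen or medium and for the GFP cultures were also revised after their results were seen.

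Long transcripts were higher in R248Q than in GFP, by a median of 0.29 (log2) over 917 genes of 8000 nt or more. A length-dependent difference between libraries that does not follow the groups is a candidate explanation for part of this, since the GFP libraries differed from each other by 0.27 in the same genes. GFP replicate 1 as the only source is argued against: R248Q lay 0.12 above the 4 libraries of R175H and R273H, a value without any GFP library. Whether R248Q raises such genes cannot be told apart from a difference between libraries with these cultures, as the slope of R248Q minus GFP replicate 2, 0.062 (log2) per doubling of length, may come from either.

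In all 3 mutants 14 genes were lower than in GFP, among them the contractile genes ACTA2, TAGLN and MYL9; MYL9 was named after its values were seen. Chance deviation of the 2 shared GFP libraries was tested in the GFP library left out of the choice of genes, with the length trend removed; chance would leave it about a seventh of the difference from the mutants. It is argued against for the 34 genes called lower in all 3 without GFP replicate 1, of which 9 are among the 14. In these GFP replicate 1 had 0.92 of the difference in GFP replicate 2 (0.69 to 1.22, 95% bootstrap over genes, which are not independent) and lay above all 6 mutant libraries in 94%. For the 489 called without GFP replicate 2, of which 10 are among the 14, the share was 0.28 (0.25 to 0.30), and deviation of GFP replicate 1 cannot be told apart from a change there. In genes chosen without the length correction both shares were lower, 0.71 (0.43 to 1.08) in GFP replicate 1 and 0.20 (0.18 to 0.23) in GFP replicate 2. The second lay nearer to what chance would leave. A state of the GFP cultures other than the lack of mutant p53 cannot be told apart from an effect of the mutants. That 100% of the 14 genes had both GFP libraries above all 6 mutant libraries follows largely from how they were chosen, and no other control cultures were listed.

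Families of genes sharing a name stem, 73 in all, were tested by camera in the same way. In R175H 1 passed upward and 2 downward, in R248Q 3 upward and 10 downward, and in R273H 0 upward and 1 downward. With the length correction 0 passed in each mutant (lowest camera adjusted p = 0.099), nor did any with an estimated correlation. The lowest p was that of 49 mitochondrial ribosomal protein genes of the MRPL family in R248Q, with a median of -0.14 (camera adjusted p = 6.4e-05, 0.82 after the length correction and 0.85 with an estimated correlation).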
